A study of Mus musculus with 10 samples.

How the data were processed

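Ulcer tissue of db/db mice was profiled by RNA sequencing in 10 libraries, 5 from ulcers given saline and 5 from ulcers given saline with Fu Huang ointment, per the labels. Total RNA was extracted with a column kit and libraries were made with a SMARTer mRNA kit, per the labels' protocols. That kit is not stated to keep strand, so a gene and its antisense partner cannot be told apart. The genome build was GRCm38 (mm10), per the submitters' processing notes. The aligner, the counting program and the annotation release are not given in the sources used here.

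The values used were estimated counts per gene, deposited by the authors as whole numbers in a single table of 55421 Ensembl gene IDs with symbols and no normalization. The table was deposited as raw counts, but among genes with 1 annotated transcript the values 4, 8, 12 and 16 occurred 6129, 3017, 1756 and 1179 times, each more often than the numbers next to it. The values 1, 2 and 3 occurred 3106, 4475 and 3025 times, so a step of 4 counts per fragment does not account for all values. The values were treated as estimated counts and not as reads. The test had been fixed for raw counts and was kept unchanged, since the deposited values were whole and needed no rounding; a fit to the values divided by 4 and rounded was added later. No column without a matching label was used, and every library was matched to its group by title and description. Locations and transcript structure came from GENCODE mouse release 21 on GRCm38, in which 55240 of the IDs were found and 181 were not. Some symbols in the table had been turned into dates by a spreadsheet, such as 1-Mar, and were left as given.

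Groups were compared with edgeR (version 4.0.16, R 4.3.3) by the quasi-likelihood F-test with robust dispersion, TMM normalization and group as the only term. Genes were tested if they passed filterByExpr with its defaults, a minimum count of 10 and a minimum total of 15, which left 18509 genes. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are ointment against saline, standard errors are those of the log2 fold change, and levels are TMM-normalized CPM (counts scaled to library size) as mean ± SD over 5 libraries. Single values per library, and the 2 genes in the study's title, were also compared by exact permutation tests over all 252 assignments of the 10 libraries, whose smallest possible p is 0.0079. Neither the labels nor the protocols say that each library came from a separate animal, so p-values measure the spread between these samples, which may be partly technical.

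The comparison, the threshold, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The lists were 41 sets of genes for cell types and pathways of wounded skin. Each was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 41 lists, and again with an estimated correlation; fry was run beside it. The lists named 8 symbols that the table did not hold. Named genes were Lpar1 and Edn1, 20 sentinel genes of wound healing, and up to 4 members with the smallest p per described list. The rule added the 10 genes with the largest change in each direction among those past the threshold with at least 5 CPM on average and no overlap between the groups, leaving out predicted and clone names. Any other gene named was chosen after its values were seen, and this is said where it occurs.

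The pipeline was tested on simulated counts for the 18509 genes with the real means, dispersions and library sizes and 100 genes changed 2-fold and 100 changed 4-fold. edgeR recovered 16% of the genes changed 2-fold and 60% of those changed 4-fold, and 0% of its 79 calls were false. DESeq2 recovered 44% and 79%, with 33.3% of its 192 calls false. A spiked list of 20 genes was called. The simulated genes were independent of each other, so the simulation does not show how often camera calls lists falsely when genes are correlated.

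The alternatives were DESeq2 size factors, upper-quartile scaling, library sizes alone, no low-count filter, a filter at 5 CPM, and a DESeq2 (1.42.0) Wald test. Others were limma voom with sample weights, a fit without robust dispersion, thresholds with a 2-fold minimum, the replicate number as a block, 1 surrogate variable from sva (3.50.0), scaling without the 50 most abundant genes, and each library left out in turn. Added after the data were seen were the values divided by 4, a fit with 4 libraries per group, and a fit without genes whose values switch between levels. Total counts per library were 47.8 to 62.9 M (M, mega), which would be 12 to 15.7 M fragments if 4 counts stood for 1 fragment.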

Results

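The data were gene counts from ulcers made by surgical excision in db/db mice, a leptin receptor mutant strain that becomes obese and diabetic. After 7 days of administration, ulcer tissue was taken from a group given saline (5 libraries) and a group given saline with Fu Huang ointment, a topical preparation (5 libraries). The comparison asks which transcripts the ointment altered in the ulcer, and the study's title singles out Lpar1 and Edn1. Totals were 58.1, 62.7, 59.1, 60.8 and 60.9 M counts (M, mega) in saline libraries 1 to 5. They were 47.8, 54.9, 62.9, 53.5 and 57.5 M in ointment libraries 1 to 5. The ointment libraries averaged 55.3 ± 5.53 M (SD, n = 5) against 60.3 ± 1.75 M, a difference that did not pass an exact permutation test (two-sided p = 0.0952). Pearson correlations of log2 CPM were 0.899 to 0.925 within groups and 0.868 to 0.916 between groups, and no libraries held identical values. The first principal component held 20.9% of the variance and placed every ointment library above every saline library (exact permutation p = 0.00794, the smallest that 252 assignments allow).

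**Figure D1:**
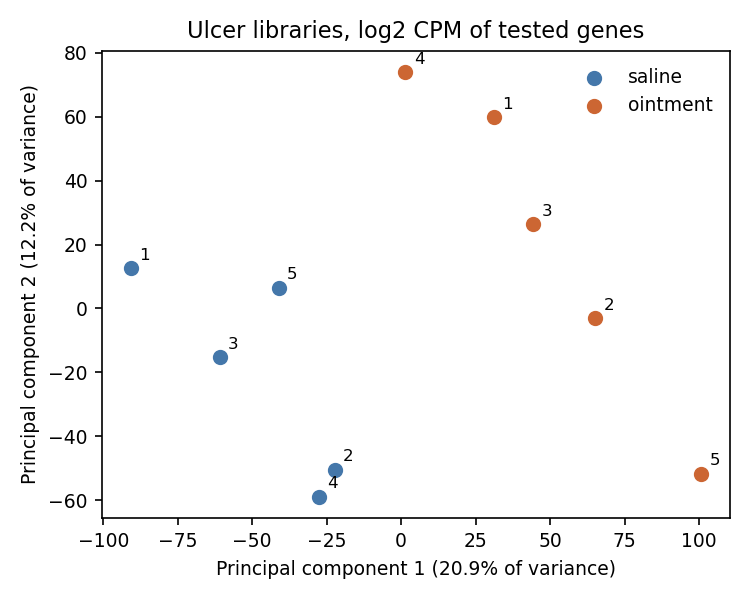
Principal components 1 (20.9% of the variance) and 2 (12.2%) of log2 CPM over the tested genes, in component units, with 1 point per library numbered by replicate. The 5 saline libraries lie at negative values of component 1 and the 5 ointment libraries at positive values, with saline 1 (-90.7) and ointment 5 (100.7) at the ends.

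With ointment, ulcers held far less transcript of the inner root sheath keratins of the growing hair follicle and of the major urinary proteins, which are small lipocalins that carry pheromones. They held more transcript of macrophage genes and of the gelatinase Mmp9. Krt71, an inner root sheath keratin, was 97.0 ± 81.9 CPM in the saline libraries and 0.276 ± 0.189 CPM in the ointment libraries (log2 fold change -8.46, SE 1.05, adjusted p = 0.00698 by edgeR with Benjamini-Hochberg adjustment). Mup22 fell from 107 ± 89.1 to 0.719 ± 0.247 CPM (log2 fold change -7.21, SE 0.81, adjusted p = 0.00432). Mmp9 rose from 92.5 ± 34.0 to 409 ± 128 CPM, a 4.42-fold difference (SE 0.30 on the log2 scale, adjusted p = 0.0143). The macrophage marker Adgre1 (F4/80) rose 1.83-fold from 148 ± 17 to 271 ± 19.4 CPM (SE 0.11 on the log2 scale, adjusted p = 0.00649). In all, edgeR called 310 of 18509 genes, 128 higher and 182 lower with ointment. Of these, 216 differed at least 2-fold (82 higher, 134 lower). In 300 of the 310 the groups did not overlap, as was true of 1211 of all tested genes (6.54%, where chance gives 0.79%). Leaving out any 1 of 8 libraries lowered the count to between 102 (without ointment 3) and 184 (without ointment 2), while it was 260 without saline 5 and 422 without ointment 4. It was 1483 with DESeq2 (751 higher, 732 lower) and 0 with the replicate number as a block. With 4 libraries per group, leaving out saline 1 and ointment 5 as the ends of the principal component, it was 59.

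Among the 10 genes with the largest increases of those without overlap between the groups, Krt2, a keratin of the upper epidermis, went from 0.257 ± 0.224 CPM with saline to 47.5 ± 24.3 CPM with ointment (log2 fold change 7.52, SE 0.73, adjusted p = 0.00273 by edgeR). The choline transporter gene Slc5a7 rose from 0.335 ± 0.147 to 10.6 ± 5.68 CPM (log2 fold change 4.98, SE 0.55, adjusted p = 0.00432). The ubiquitin-like modifier gene Ubd rose from 0.967 ± 0.399 to 12.9 ± 5.20 CPM (3.73, SE 0.41, adjusted p = 0.00432). Npr3, the clearance receptor for natriuretic peptides, rose 10.4-fold from 5.38 ± 3.26 to 55.7 ± 15.9 CPM (adjusted p = 0.0172). Tceanc2 rose 6.79-fold (adjusted p = 0.0124). The macrophage scavenger receptor gene Marco (log2 fold change 3.90, adjusted p = 0.0309) and the macrophage product Cd5l (2.79, adjusted p = 0.0457) rose. The anion exchanger gene Slc26a4 (7.17, adjusted p = 0.04) and Mal (2.29, adjusted p = 0.0339) rose as well. Mmp9 was the last of the 10. Krt2, Slc5a7, Ubd, Npr3, Tceanc2 and Mmp9 passed the threshold whichever library was left out. Marco, Cd5l, Slc26a4 and Mal passed in 3, 1, 2 and 3 of those 10 fits, with adjusted p reaching 0.0753, 0.116, 0.0875 and 0.086.

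The 10 largest decreases by the same rule were of 5 inner root sheath keratins (Krt25, Krt71, Krt73, Krt27 and Krt28) and 5 major urinary protein genes (Mup7, Mup22, Mup10, Mup11 and Mup18). Krt25 was 67.4 ± 59.0 CPM in the saline libraries and 0.165 ± 0.296 CPM in the ointment libraries, 3 of which were at 0 (log2 fold change -8.72, SE 1.48, adjusted p = 0.0233 by edgeR). The keratins varied between saline ulcers: Krt71 ran from 4.68 CPM in saline 5 to 223 CPM in saline 1, while no ointment library exceeded 0.579 CPM. Mup7 was 20.4 ± 13.7 CPM with saline and 0.0362 ± 0.0518 CPM with ointment (log2 fold change -9.13, SE 0.94, adjusted p = 0.00411). Mup10, Mup11 and Mup18 fell by 5.53, 5.14 and 5.05 on the log2 scale. The Mup genes, on chromosome 4, are near-identical copies whose reads the counting could have split, so values of single members are uncertain. Summed over the family they were 218 ± 99.9 CPM with saline and 3.64 ± 1.39 CPM with ointment (exact permutation p = 0.0079, adjusted 0.012 over scores chosen afterwards). The family was chosen after 5 of its members led the decreases under a rule of no overlap. The small p of the sum therefore follows largely from that choice and is not independent evidence. The calls of the 5 Mup genes, Krt71 and Krt27 held whichever library was left out. Krt25 lost its call without saline 1, ointment 2, ointment 3 or ointment 5 (adjusted p up to 0.0616), Krt73 without ointment 5 (0.0571), and Krt28 in 8 of the 10 fits (up to 0.101).

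**Figure D2:**
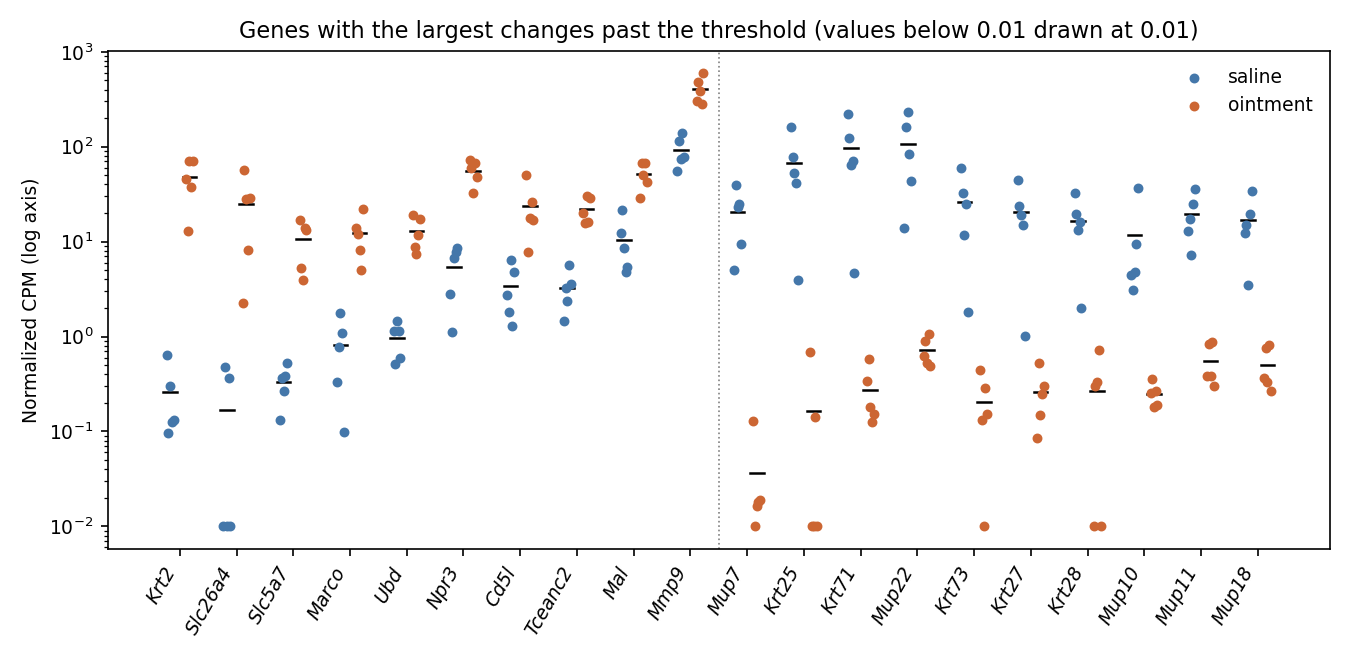
Normalized CPM per library on a log axis for the 10 genes with the largest increases (left of the dotted line) and the 10 with the largest decreases (right), with values under 0.01 drawn at 0.01. Points are libraries (5 saline, 5 ointment) and bars are group means; the choice of genes required groups without overlap.

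Lpar1, a receptor for lysophosphatidic acid (LPA; chromosome 4, 58435255 to 58553898), was 43.0 ± 26.5 CPM in the saline ulcers and 46.1 ± 27.7 CPM in the ointment ulcers, a difference within the spread between libraries (log2 fold change 0.10, SE 0.46, adjusted p = 0.949 by edgeR; exact permutation p = 0.825). Edn1, which encodes the vasoconstrictor peptide endothelin 1 (chromosome 13, 42301476 to 42307990), was 8.90 ± 1.66 CPM with saline and 6.29 ± 2.20 CPM with ointment and did not pass either test (log2 fold change -0.50, SE 0.27, adjusted p = 0.381 by edgeR; exact permutation p = 0.0714). The 95% confidence intervals of the log2 fold changes were -0.93 to 1.13 for Lpar1 and -1.09 to 0.09 for Edn1. Lpar1 was 89.2 CPM in saline 1 and 21.8 to 36.1 CPM in the other saline libraries, and its estimate turned to -0.08 without saline 4 and to -0.30 without ointment 2. Of the 10 LPA receptor and enzyme genes tested, none passed the threshold, and adjusted over the list alone 1 was higher and 1 lower. The LPA-producing enzyme gene Enpp2 had a log2 fold change of 0.67 (adjusted p = 0.0979), Lpar2 -0.78 (0.136), Plpp1 0.26 (0.371) and Lpar5 1.75 (0.377). The list was not called (median log2 fold change 0.18, adjusted p = 0.37 by camera).

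The endothelin genes had mostly negative fold changes, and their call as a list was not stable. Of the 7 tested, Edn2 fell from 1.43 ± 0.930 to 0.229 ± 0.0874 CPM (log2 fold change -2.63, SE 0.50, adjusted p = 0.0336 by edgeR). The other 6 did not pass, including Edn3 (-1.12, adjusted p = 0.202), Ece2 (-0.57, 0.307) and the receptor gene Ednrb, the single member with a positive value (0.55, 0.245). The list's median log2 fold change was -0.57 and camera gave an adjusted p of 0.036, with adjusted p = 0.36 with an estimated correlation. Adjusted over the list alone, 1 gene was lower. The list's call was lost without saline 2 (adjusted p = 0.12) or ointment 4 (0.085), with values divided by 4 (0.11), with limma voom (0.055) and with the replicate number as a block (0.082). Edn2 lost its call in 8 of the 10 fits with a library left out (adjusted p up to 0.084).

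**Figure D3:**
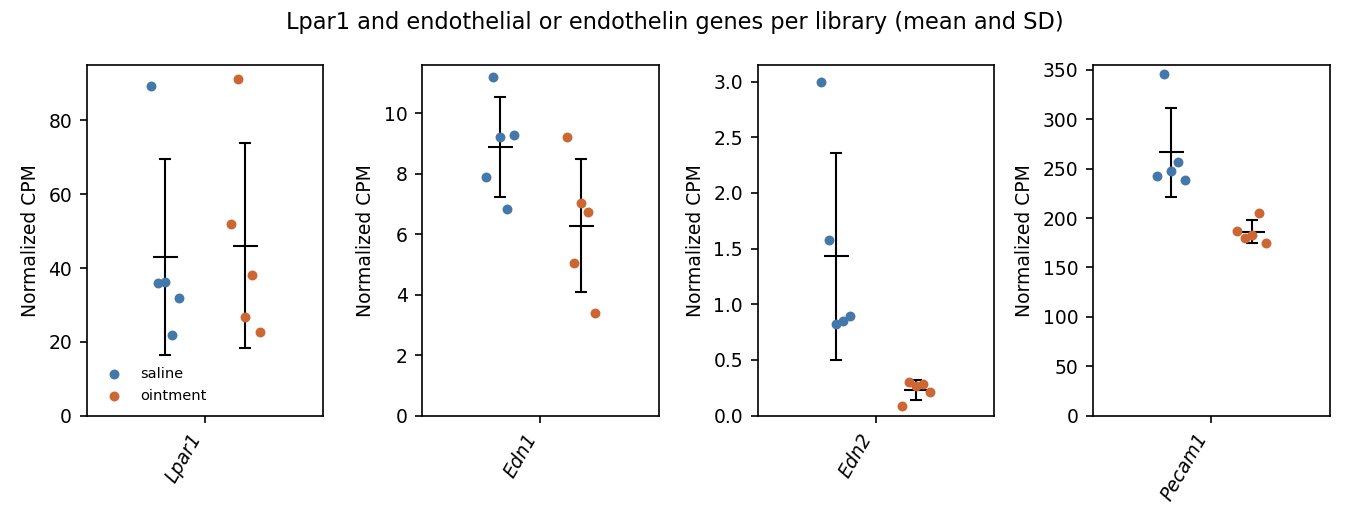
Normalized CPM per library of Lpar1, Edn1, Edn2 and Pecam1 on linear axes from 0, with 1 point per library, 5 per group, and the mean and SD in black. Lpar1 and Edn1 overlap between the groups, while Edn2 and Pecam1 are lower in every ointment library than in every saline library, past the threshold for Edn2 alone.

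Markers of blood vessels had lower values with ointment. None of the 16 endothelial markers tested passed the threshold alone, but 15 had negative fold changes. Pecam1 (CD31) was 266 ± 44.8 CPM with saline and 186 ± 11.4 CPM with ointment (log2 fold change -0.52, adjusted p = 0.0646 by edgeR). Esam (-1.12, adjusted p = 0.166), Vwf (-0.82, 0.168) and Sox18 (-0.75, 0.197) also had negative values. The endothelial list was called lower (median -0.44, adjusted p = 0.002 by camera; adjusted p = 0.58 with an estimated correlation). All 9 pericyte markers had negative fold changes and none passed alone. Notch3 was at -1.02 (adjusted p = 0.0604), Rgs5 at -1.38 (0.201), Kcnj8 at -0.95 (0.274) and Cspg4 at -0.54 (0.273). The pericyte list was called lower (median -0.74, adjusted p = 0.0019; adjusted p = 0.37 with an estimated correlation). Of 11 smooth muscle and myofibroblast markers, Myh11, the smooth muscle myosin heavy chain, fell 1.78-fold (adjusted p = 0.04). The other 10 did not pass, among them Lmod1 (-0.75, adjusted p = 0.121), Cnn1 (-0.83, 0.196) and Des (0.97, 0.251). That list was called lower (median -0.45, adjusted p = 0.0067; adjusted p = 0.58 with an estimated correlation) but not with 4 libraries per group (0.061). Myh11 passed in none of the 10 fits with a library left out (adjusted p up to 0.0956). Adjusted over the list alone, 1 endothelial, 1 pericyte and 2 smooth muscle genes were lower. The 23 angiogenic factors and receptors showed no common direction (median 0.02, mean 0.04, camera direction down, adjusted p = 0.96). Vegfc was at 0.79 (adjusted p = 0.079), Dll4 at -0.65 (0.195), Pgf at 1.24 (0.267) and Hgf at 0.64 (0.307). Vegfa (0.52, adjusted p = 0.57) and Kdr (-0.27, 0.638) did not pass.

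Macrophage genes were higher with ointment. All 17 macrophage and monocyte markers had positive fold changes and 3 rose. These were Adgre1, the lysosomal marker Cd68 (157 ± 14.3 to 269 ± 27.4 CPM, 1.71-fold, adjusted p = 0.0125 by edgeR) and the lipid receptor gene Trem2 (1.78-fold, adjusted p = 0.0325). Csf1r did not pass (0.55, adjusted p = 0.0816). This list was called at adjusted p = 2.9e-06 by camera and also with an estimated correlation (adjusted p = 0.037), the only one of the 41 lists for which both held. No list was called with an estimated correlation in 8 of the 10 fits with a library left out, with the replicate number as a block or with 4 libraries per group, so that second call was not stable. In it, 7 members were higher when adjusted over the list alone. None of the 15 genes of alternatively activated macrophages passed alone. Chil3 was at 3.40 (adjusted p = 0.0533), Clec10a at 1.07 (0.0578), Pdcd1lg2 at 1.09 (0.0987) and Mrc1 at 0.59 (0.108). Of the 15, 12 were positive, and the list was called higher (median 0.72, adjusted p = 0.0015; adjusted p = 0.11 with an estimated correlation). Adjusted over the list alone, 8 of them were higher and 2 lower. Arg1 had a log2 fold change of 2.46 (adjusted p = 0.143). Adgre1 and Cd68 passed whichever library was left out, and Trem2 passed in 4 of the 10 fits (adjusted p up to 0.0838).

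Neutrophil and cytokine genes had higher means with ointment and a wide spread. None of 17 neutrophil markers passed alone, 15 were positive, and the list was called higher (median 1.45, adjusted p = 3.1e-05 by camera; adjusted p = 0.58 with an estimated correlation). Mmp8 was at 2.79 (adjusted p = 0.0635 by edgeR), Cxcr2 at 2.13 (0.132), S100a8 at 1.26 (0.13) and Ltf at 1.45 (0.113). Adjusted over the list alone, 8 were higher. None of 22 pro-inflammatory cytokine and chemokine genes passed and 19 were positive. Cxcl1 was at 4.26 (adjusted p = 0.0895), Il6 at 3.29 (0.116), Ccl7 at 1.43 (0.148) and Cxcl3 at 3.22 (0.163). This list was called higher (median 1.38, adjusted p = 0.0035; adjusted p = 0.65 with an estimated correlation) and 0 were called when adjusted over the list alone. Ointment 5 held the highest values of the named cytokine and chemokine genes, such as 5120 CPM of Il1b against 243 to 745 CPM in the other ointment libraries. The cytokine list was not called without ointment 5 (adjusted p = 0.081), without saline 1 (0.13) or with 1 surrogate variable (0.1). With 4 libraries per group its direction turned to lower, without a call (adjusted p = 0.63). Without ointment 5 the estimates of Il1b (1.30, adjusted p = 0.601) and Cxcl2 (1.40, 0.618) turned to -0.07 and -0.04. Tnf did not pass (1.45, adjusted p = 0.2).

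Hair follicle genes were lower in the ointment ulcers. Of 20 tested, 9 fell, 11 did not pass and 19 had negative fold changes. Besides the keratins, the transcription factor genes Hoxc13 (6.29 ± 2.09 to 1.30 ± 0.280 CPM, log2 fold change -2.28, adjusted p = 0.00698 by edgeR) and Lef1 (-1.97, adjusted p = 0.0143) fell. The list's median was -2.93 (adjusted p = 2.5e-13 by camera; adjusted p = 0.23 with an estimated correlation), and 15 were lower when adjusted over the list alone. Of 8 melanocyte genes, the 4 pigment genes Dct (-2.04, adjusted p = 0.0165), Tyrp1 (-2.47, 0.0285), Slc45a2 (-2.87, 0.0406) and Tyr (-2.43, 0.0442) fell and 4 did not pass. In this list 7 were lower when adjusted over the list alone (median -2.16, adjusted p = 1.2e-06 by camera; adjusted p = 0.22 with an estimated correlation). Of 13 Schwann cell and nerve genes, Sox10 fell (-1.45, adjusted p = 0.0401). The other 12 did not pass, including Ngfr (-0.85, 0.0913), L1cam (-0.91, 0.117) and Egr2 (-1.25, 0.285). As a list they were called lower (median -0.60, adjusted p = 0.0067; adjusted p = 0.58 with an estimated correlation), with 3 lower when adjusted over the list alone. The Schwann list was not called without saline 1 (adjusted p = 0.1), with 1 surrogate variable (0.068) or with 4 libraries per group (0.13). Hoxc13, Lef1 and Dct passed whichever library was left out. Tyrp1, Slc45a2, Tyr and Sox10 passed in 3, 1, 1 and 1 of the 10 fits (adjusted p up to 0.0798, 0.103, 0.113 and 0.0976).

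Genes of the epidermis went both ways. Of 28 genes of differentiated and cornified keratinocytes, Krt2 rose and 2 fell. These were the desmosomal cadherin gene Dsc1 (189 ± 24.9 to 89.0 ± 14.8 CPM, log2 fold change -1.09, adjusted p = 0.00823 by edgeR) and Krtdap (-0.997, adjusted p = 0.0222). The other 25 did not pass, among them Sbsn (-0.85, adjusted p = 0.0563) and Krt10 (-1.80, adjusted p = 0.0778). The list was not called (median -0.88, adjusted p = 0.087 by camera), and adjusted over the list alone 3 were higher and 11 lower. Of 15 basal keratinocyte markers, the laminin chain gene Lamb3 rose (2.52-fold, adjusted p = 0.0218). The other 14 did not pass, including Dsp (-0.89, adjusted p = 0.124), Pkp1 (-0.89, 0.239), Perp (-1.44, 0.25) and Krt14 (-0.21, 0.659). Adjusted over the list alone 1 was higher, and the list lay at the threshold without passing it (median -0.31, adjusted p = 0.05). Of 21 wound-activated keratinocyte genes, the growth factor gene Hbegf rose (20.2 ± 7.37 to 54.9 ± 17.5 CPM, 2.72-fold, adjusted p = 0.0379). The other 20 did not pass, including Slpi (1.99, adjusted p = 0.0817), Lama3 (1.46, 0.0964), Sprr1b (3.51, 0.21) and Krt16 (-0.17, 0.747). That list was called higher (median 0.79, adjusted p = 0.009; adjusted p = 0.58 with an estimated correlation), with 3 higher when adjusted over the list alone. Dsc1 passed whichever library was left out. Krtdap, Lamb3 and Hbegf passed in 5, 8 and 2 of the 10 fits (adjusted p up to 0.0654, 0.061 and 0.0904). Sprr1b turned to -0.08 without ointment 4.

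Genes of the stress and metabolic lists rose in part. Of 18 NRF2 and oxidative stress genes, the NADPH oxidase subunit gene Ncf1 (2.88-fold, adjusted p = 0.0166 by edgeR) and the superoxide dismutase gene Sod1 (1.39-fold, adjusted p = 0.0349) rose. The other 16 did not pass, including Hmox1 (1.10, adjusted p = 0.0757) and Ager (0.62, 0.162). Of the 18, 3 were higher when adjusted over the list alone, and the list was called higher (median 0.42, adjusted p = 0.0029 by camera; adjusted p = 0.36 with an estimated correlation). Of 13 glucocorticoid response genes, the kinase gene Pdk4 (29.4 ± 8 to 91.0 ± 31.4 CPM, 3.10-fold, adjusted p = 0.0298) and the clock gene Per1 (2.53-fold, adjusted p = 0.0412) rose. The other 11 did not pass, including Mt1 (0.97, adjusted p = 0.22) and Tsc22d3 (0.71, 0.252). Of the 13, 2 were higher when adjusted over the list alone, and the list was called higher (median 0.97, adjusted p = 0.0015; adjusted p = 0.38 with an estimated correlation). None of 20 gene IDs for the 19 hypoxia and glycolysis symbols passed and 18 were positive. Car9 was at 1.35 (adjusted p = 0.103), Adm at 0.82 (0.253), Pfkfb4 at 0.57 (0.277) and Tpi1 at 0.41 (0.357). The hypoxia list was called higher (median 0.42, adjusted p = 0.0067; adjusted p = 0.65 with an estimated correlation) but not without ointment 5 (0.17), with 1 surrogate variable (0.16) or with 4 libraries per group (0.21). In it 0 were called when adjusted over the list alone. Of 20 adipocyte genes, the fatty acid transporter gene Cd36 (214 ± 47.7 to 780 ± 124 CPM, 3.65-fold, adjusted p = 0.00205) and leptin, Lep (17.9-fold, adjusted p = 0.0347), rose. Lep was 8.45 CPM in ointment 2, within the saline range of 2.96 to 15.9 CPM, and 111 to 261 CPM in the other ointment libraries. Adipsin, Cfd, fell (log2 fold change -2.80, adjusted p = 0.0384). The other 17 did not pass, including Plin1 (1.24, 0.0763). The adipocyte list was not called (median 0.61, adjusted p = 0.1), with 8 higher and 3 lower when adjusted over the list alone. Cd36 and Ncf1 passed whichever library was left out. Sod1, Pdk4, Per1, Lep and Cfd passed in 3, 3, 2, 2 and 1 of the 10 fits (adjusted p up to 0.0921, 0.0749, 0.0982, 0.087 and 0.0948).

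**Figure D4:**
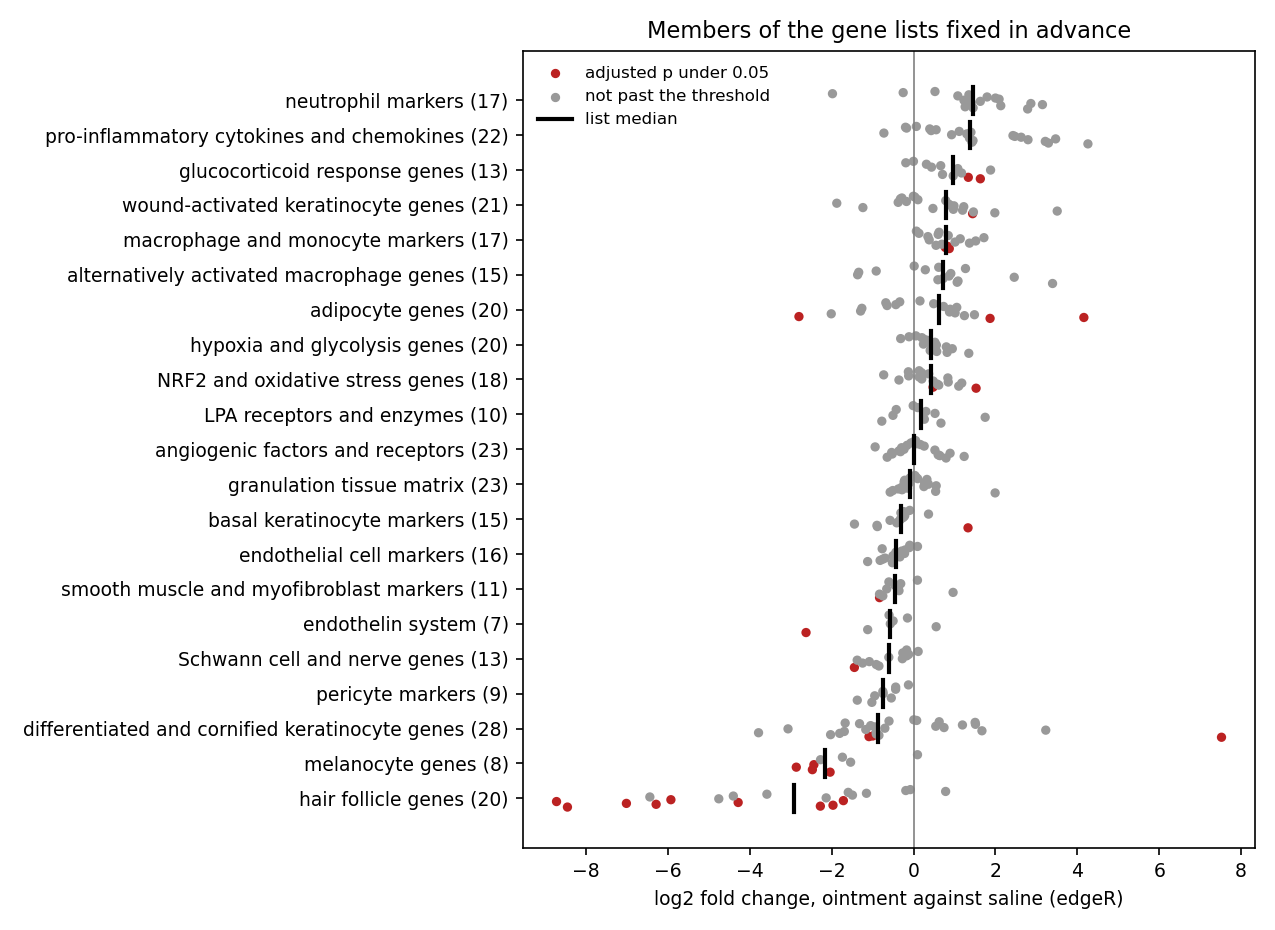
Log2 fold changes, ointment against saline, of the members of 21 gene lists, with 1 point per tested gene (number in brackets), red where the adjusted p was under 0.05, and a black bar at each list's median. Medians run from 1.45 for neutrophil markers to -2.93 for hair follicle genes.

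For matrix and proliferation genes no difference passed, and the proliferation list depended on the fit. None of 23 granulation tissue matrix genes passed. Thbs1 was at 1.99 (adjusted p = 0.175 by edgeR), Ctsk at -0.57 (0.23), Col12a1 at 0.54 (0.335) and Postn at -0.51 (0.59). The matrix list was not called (median -0.08, mean 0.06, camera direction down, adjusted p = 0.65). Col1a1 (-0.23, adjusted p = 0.85), Col3a1 (-0.37, 0.655), Fn1 (-0.15, 0.672), Acta2 (-0.31, 0.594), Timp1 (1.10, 0.438) and Mki67 (-0.07, 0.924) did not pass either. Mki67 turned to 0.17 without saline 4 and to 0.01 without ointment 4. Of 23 cell proliferation genes, 18 were positive and the list was not called (median 0.14, adjusted p = 0.062), but it was in 5 of 24 alternatives (0.00018 to 0.95 over all 24). Adjusted p by camera was 0.29 for fibroblast markers, 0.11 for metalloproteases and the plasmin system and 0.19 for TGF-beta signalling. Lymphocyte lists were not called either, at 0.92 for T cells, 0.85 for natural killer cells and 0.38 for B and plasma cells. Nor were dendritic and Langerhans cells (0.47), mast cells (0.1), erythrocytes (0.46) and lymphatic endothelium (0.51, median -0.07 and mean 0.19). The remaining lists without a call were sebaceous gland (0.25), skeletal muscle (0.1), interferon response (0.45, median -0.19 and mean 0.02), oxidative phosphorylation (0.36), insulin and leptin signalling (0.92), aryl hydrocarbon receptor targets (0.96, median -0.12 and mean 0.04), circadian clock (0.47), immediate early genes (0.79, median 0.01 and mean -0.01) and heat shock (0.19). Other lists without a call were called in some of the 24 alternatives, namely basal keratinocyte in 7, cornified keratinocyte in 5, adipocyte in 4, skeletal muscle in 3, metalloproteases and mast cells in 2 each, and sebaceous gland, immediate early and heat shock in 1 each. Camera called 15 of the 41 lists, 8 higher and 7 lower. It called a median of 9 lists under other splits of the 10 libraries, so a list's call alone may be due to chance. The fry test, which asks whether a list's own genes moved, called 7 in 1 direction and 25 in either.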

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

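The tests of the Mup and follicle patterns, and the test on single-exon genes, were chosen after the result was seen; the other tests of switching values and the counts over other splits were chosen before.

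Within a group of 5, 22 of the 238 groups of values tested held a library far from the other 4 (a gap of more than 0.71 of the group's range). Chance would give about 11.9 for normally distributed values. CPM on a linear scale can be skewed, and 21 of the 22 lay on the high side, so the excess over chance is uncertain. Ointment 5 held 7 of the 22, all highest: 5120 CPM of Il1b (243 to 745 in the other ointment libraries), 97.3 CPM of Il6 (4.25 to 22.9), 4110 CPM of Cxcl2 (119 to 749), 322 CPM of Cxcl1 (9.23 to 58.7), 331 CPM of Ccl7 (101 to 156), 309 CPM of Chil3 (50.6 to 119) and 1590 CPM of Slpi (267 to 646). Saline 1 held 89.2 CPM of Lpar1 (21.8 to 36.1 in the other saline libraries), 2.21 CPM of Cxcl2 (505 to 582), the single value flagged on the low side, and 1510 CPM of Dsp (696 to 880). On a linear scale low values are less easily flagged. Saline 1 also held 8.86 CPM of Il1b (611 to 892) and 0.749 CPM of Cxcl3 (25.5 to 117), neither of them flagged. Saline 5 held 36.5 CPM of Mup10 (3.12 to 9.38), 12.5 CPM of Cxcl1 (1.08 to 3.97), 31.3 CPM of Chil3 (3.46 to 10.1) and 103 CPM of Sod1 (84.8 to 89.0). In the other saline libraries, Pecam1 reached 346 CPM in saline 2 (238 to 257), Mki67 415 CPM in saline 4 (192 to 250), and saline 3 held 182 CPM of Cd68 (148 to 155) and 734 CPM of Cfd (236 to 339). Ointment 1 held 0.128 CPM of Mup7 (0 to 0.0189) and 0.682 CPM of Krt25 (0 to 0.143), and ointment 4 held 997 CPM of Des (312 to 465) and 253 CPM of Sprr1b (3.13 to 5.66).

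Of the 126 ways to split the 10 libraries 5 against 5, 100 were drawn, the real one included. The real split called 310 genes by edgeR and the highest of the others 4, so only 1 of the 100 splits gave as many. A chance split of these libraries is thus unlikely to account for the count of genes. The splits do not address chance between animals, since the libraries may not be separate animals. The real split called 15 lists by camera and the highest of the others 21; 15 splits called as many, so chance cannot be excluded for the count of lists.

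Major urinary protein transcripts were lower in every ointment library, with 67.6 to 324 CPM for the family in the saline libraries and 2.14 to 5.50 CPM in the ointment libraries. Reads moving between the copies would leave their sum unchanged, but it differed by -5.81 on the log2 scale, beyond the spread between libraries (SD 0.897 and 0.581). RNA from liver is also argued against: abundant liver transcripts summed to 0.0204 of the Mup total in the saline libraries. The adipocyte genes other than Cfd had a median log2 fold change of 0.73, where a loss of fat cells needed -1 or lower. That median left out Cfd, which fell (-2.80), and of the 20 adipocyte genes 12 were positive and 8 negative. With Cfd included, the mean log2 CPM of the list was 5.18 ± 0.54 with saline and 5.43 ± 0.3 with ointment. Cfd had the lowest fold change of the 20, a smaller fall than the -5.81 of the Mup sum. For these 20 genes, the values argue against a loss of fat cells large enough to account for the Mup decrease. A different genotype on chromosome 4, which carries the Mup cluster and Lepr, cannot be told apart from the groups. Lepr itself fell (log2 fold change -1.24, adjusted p = 0.0199 by edgeR). Besides it, only 2 called genes, Itgb3bp and Tceanc2, lay among 112 tested within 10 Mb of Lepr (odds ratio 1.11, 95% interval 0.133 to 4.16, Lepr and Mup genes left out). Lepr starts at position 101717404, while the named Mup genes lie between 60066469 and 61674136. That window did not reach the Mup cluster, so it cannot decide whether the genotype differed there. A different genotype and the treatment itself stay open.

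Hair follicle genes were lower in every ointment library, by 3.27 in the mean log2 CPM of the list. The exact permutation p was 0.0079 (n = 5 per group), or 0.012 when adjusted over the scores chosen afterwards. Adjusted over all the gene lists tested, the same permutation test gave 0.065 and did not pass. The unadjusted p was already the smallest that 252 assignments allow. The adjusted value thus depended on how many lists shared that p, and no conclusion is drawn from it. A smaller share of follicle-bearing skin in the samples would lower the sebaceous glands of the same follicles alike. The follicle score less the sebaceous score, however, differed by -3.03 (SD 1.02 and 0.584). That comparison counts only if no other cells of the ulcer express the sebaceous genes, which was not tested. A smaller share of follicle-bearing skin therefore stays open. Dilution by immune cells would lower basal keratinocyte genes alike, but the follicle score less the basal keratinocyte score differed by -2.92 (SD 1.13 and 0.355). A lower share of growing follicles in the ointment ulcers is a hypothesis that was not tested; whether the decrease came from the treatment, the hair cycle at excision or the site sampled stays open.

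Some values switched between levels from library to library, without regard to the groups: mt-Cytb had 390595, 230989, 314385 and 259679 counts in saline 3 and ointment 1, 3 and 5 and 0 in the other 6 libraries, and 254 of 8339 genes with 20 CPM or more fell into separate levels at least 2-fold apart. Treatment is argued against, since 0% of these genes split by group, and so is assignment of reads among a gene's annotated transcripts, since genes with several transcripts switched less often than genes with 1 (risk ratio 0.219; 2.43% against 11.1%). Genes with only single-exon transcripts switched in 38 of 98 cases against 216 of 8241 spliced genes (risk ratio 14.8; 7.07 among genes with 1 annotated transcript). A candidate explanation is that reads were assigned in some libraries to assembled transcripts outside the gene table, since an unspliced gene has no junction to tie its reads to the annotated model. Among genes of 20 CPM or more, none of the named genes was counted as switching and 1 called gene was (Hs2st1, named after its values were seen). The count required a gap of at least 60% of a gene's range, so named genes are not shown to be free of switching. Perp was at 272 to 318 CPM in ointment 3, 4 and 5 and at 1270 CPM or more in the other libraries. Genes apart in a single library, such as Sprr1b in ointment 4, could not be counted. Genes under 20 CPM were not screened. Members of the lists did switch, such as Cldn5, at 0 CPM in ointment 1 and 2, and Lpar6, at 0 CPM in saline 5 and ointment 3.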

How the results depend on the processing

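The fits to values divided by 4, with 4 libraries per group and without switching genes were chosen after the data were seen; the other alternatives were planned. Against 310 genes (128 higher, 182 lower), the DESeq2 Wald test called 1483 (751 and 732), an unadjusted p with a 2-fold minimum 1168 (616 and 552), and 4 libraries per group 59 (21 and 38); the number higher was 85 without a low-count filter and 82 with a 2-fold minimum. Leaving out 1 library at a time gave 102 to 422 genes, 45 to 199 higher and 55 to 223 lower, and 80 of the 310 genes were called in all 10 of these fits. All 310 were among DESeq2's calls, and on simulated data 33.3% of DESeq2's calls were false. That share came from a single run with 100 genes changed at each fold, so it need not hold for the 1483 calls here. Fewer libraries lower the power, and no other cause was tested.

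With the replicate number as a block edgeR called 0 genes (0 higher, 0 lower), against 2602 at an unadjusted p under 0.05, and 14 lists; the endothelin list was the only list whose call changed (adjusted p = 0.082). Same-numbered libraries did not deviate together (correlations 0.056, 0.006, -0.073, -0.077 and -0.059), and only saline 1 was the best match of its own number. The values thus gave no sign of pairing by number, but the labels do not say whether the numbers pair animals.

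The share of calls that were higher was 41.3%, from 32.7% without saline 5 to 52.7% with an unadjusted p and a 2-fold minimum; it was 36.3% with library sizes alone, 49.6% with 1 surrogate variable (266 genes, 12 lists) and 50.6% with DESeq2. Scaling moved the median of all genes by at most 0.06 (log2). Lists called numbered 12 to 19 over the alternatives. Of 43 called named genes, 12 passed in every alternative but the block. Edn1 kept its direction and did not pass in any of 26 alternatives (-0.68 to -0.34), while Lpar1 (0.10) was 0.72 with 4 libraries per group, was -0.30 to 0.54 over the fits with a library left out, and turned to -0.08 without saline 4 and -0.30 without ointment 2. None of the reversals were of called genes: Il1b was -0.14 with the surrogate variable, -0.07 without ointment 5 and -0.39 with 4 libraries per group; Cxcl2 was -0.36, -0.04 and -0.36 in the same fits; Mki67 was 0.17 without saline 4 and 0.01 without ointment 4; and Sprr1b was -0.08 without ointment 4. With a library left out, Il1b reached 1.58, Cxcl2 1.70, Mki67 -0.16 at the lowest and Sprr1b 3.81. The cause was not tested beyond the single libraries named. Depth limits low genes: if 4 counts stood for 1 fragment, a value such as 0.0362 CPM of Mup7 would be about 1 fragment or fewer per library.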

Other observations

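The genes in this part were chosen after their values were seen, so they stand for single genes and not for pathways.

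Single genes of metabolism differed in both directions. The lipid droplet coat gene Plin2 went from 313 ± 42.5 to 801 ± 96.9 CPM (log2 fold change 1.36, SE 0.13, adjusted p = 0.00205 by edgeR) and Angptl4, an inhibitor of lipoprotein lipase, from 153 ± 39.0 to 323 ± 52.6 CPM (1.08, SE 0.20, adjusted p = 0.0305). The thioredoxin-binding protein gene Txnip was 356 ± 69.6 CPM with saline and 677 ± 81.0 CPM with ointment (0.93, SE 0.15, adjusted p = 0.0178). Lepr, the gene mutated in db/db mice, was 21.5 ± 3.48 CPM with saline and 9.11 ± 2.38 CPM with ointment (-1.24, SE 0.20, adjusted p = 0.0199). Cyp2e1 fell from 66.1 ± 44.0 to 2.20 ± 1.68 CPM (-4.90, SE 0.90, adjusted p = 0.0309). Each of these 5 genes differed without overlap between the groups.

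Higher with ointment were also the leukocyte integrin gene Itgb2 (91.4 ± 16.9 to 226 ± 55.4 CPM, log2 fold change 1.31, adjusted p = 0.0159 by edgeR), Rac2 (1.29, adjusted p = 0.0341) and the cathepsin gene Ctss (732 ± 96.7 to 1401 ± 236 CPM, 0.94, adjusted p = 0.0159). Lower were the hedgehog effector gene Gli1 (21.7 ± 6.80 to 3.77 ± 1.88 CPM, -2.52, adjusted p = 0.0165), Sostdc1 (-2.61, adjusted p = 0.00627) and Lhx2 (-2.37, adjusted p = 0.0175). The water channel gene Aqp3 was 185 ± 55.7 CPM with saline and 66.2 ± 17.1 CPM with ointment (-1.48, adjusted p = 0.0183).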
